A study of Mus musculus with 17 samples.

How the data were processed

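RNA was sequenced in bulk from haematopoietic stem cells (HSCs) of C57BL/6 Jrj mice. Per the labels, bones were crushed in ice-cold buffer, marrow was enriched for c-kit, and HSCs were sorted into trizol as CD150+ CD48- cells among Sca1+ cKit+ cells without lineage markers. Libraries were made with a Nextera XT protocol at reduced volume. The 17 libraries formed 4 groups by the labels: young control (n = 4), young CCCP (n = 5), old control (n = 3) and old Mito-Q (n = 5). Young mice were 8 to 12 weeks old and old mice were over 18 months old. CCCP, a protonophore that uncouples mitochondria, was given as 1 injection of 0.3 mg/kg. Mito-Q, a ubiquinone antioxidant that accumulates in mitochondria, was given as 5 daily injections of 2 mg/kg. The labels did not say whether controls received vehicle, how long after the last injection cells were taken, or whether each library came from a separate mouse. The p-values therefore measure the spread between libraries.

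The authors trimmed reads with Trim Galore, aligned them with STAR 2.7 to GRCm38, and deposited raw read counts per Ensembl gene for each library. The counting program, annotation release, strand setting and any removal of duplicate reads were not stated. Each deposited file gave counts for 54838 genes and 5 footer entries for reads assigned to no gene, which were kept apart. GENCODE M21, an annotation of the same build, gave names, coordinates and biotypes for 54723 of the gene IDs. Gene totals ran from 5649611 to 8120443 reads per library. A count of 3 reads, used as the floor, corresponded to between 0.296 and 0.649 CPM (counts scaled to library size). The floor covers counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. No pair of libraries within a group was a duplicate, as the lowest chi-square per degree of freedom between their counts was 20.9.

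All 17 libraries were fitted together in edgeR 4.0.16 under R 4.3.3, with TMM factors, filterByExpr by group (minimum count 10) and robust quasi-likelihood dispersions. No covariate was used. Of the genes in the files, 24523 were tested by the two-sided quasi-likelihood F-test, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Old control was compared with young control, old Mito-Q with old control, young CCCP with young control and old Mito-Q with young control. CPM values in the text carry TMM factors and are given as mean ± SD. Fold changes are log2 estimates from the fit with their standard errors (SE).

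Gene lists, 42 in number, covered metabolism, mitochondria, stress, inflammation, HSC ageing and identity, cell cycle, gene expression, blood lineages and other cell types of the marrow. They were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. Correlations between the fold changes of 2 comparisons were set beside 100 simulations with no group effect, because comparisons that share control libraries correlate without any effect. The share of ageing genes with an opposite or the same sign under treatment was set beside 100 simulations with the fitted ageing effect and no treatment effect. A simulation with 1 level per age fitted over controls and treated libraries together had been computed first, and its values are given too. All these simulations drew genes independently, without the correlation between real genes, so their spread is too narrow. Intervals of shares are exact Clopper-Pearson 95% intervals. They treat genes as independent, which genes measured in the same libraries are not, and do not measure the spread between libraries.

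Genes to be named were set by rule. For the first 3 comparisons these were up to 12 higher and 12 lower called genes of smallest p with an average log2 CPM above 2, leaving out predicted and clone-named models, and 4 members of each called list. The HSC ageing, HSC identity and mitochondrial DNA lists gave 4 members each whether called or not, and each list of other cell types gave its 3 members of highest mean count. For old Mito-Q versus young control up to 6 higher and 6 lower genes were named. Any other gene is said to have been chosen after its values were seen. The groups, comparisons, tests, lists and this rule were fixed before the data were examined.

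The procedure was tested on simulated data with 200 changed genes per comparison. Planted 2-fold changes were called in 1.49% to 4.48% of genes, 4-fold changes in 41.8% to 49.3% and 8-fold changes in 54.5% to 71.2%. False calls made up between 1.41% and 6.25% of the calls. Small changes were thus mostly below what these libraries could show.

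Alternatives included other scalings (DESeq2 size factors, upper-quartile factors, library totals), other filters, DESeq2 1.42.0, limma-voom with quality weights, covariates for depth, a replicate block, fits of only the groups compared and leaving out each library in turn. Further alternatives were added after the data had been seen. They left out libraries with many reads outside genes or with low correlation, used the share of such reads or the neutrophil list as a covariate, removed ribosomal RNA genes, separated directions, and removed immediate early genes from the results or from other lists. Drawings were made with matplotlib 3.10.9.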

Results

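Transcript levels were measured by RNA sequencing in sorted HSCs from young mice, young mice given CCCP, old mice and old mice given Mito-Q. The comparisons asked how HSCs of old mice differed from those of young mice, and how a mitochondrial uncoupler in young mice or a mitochondrial antioxidant in old mice altered their transcripts. Gene totals ran from 5649611 reads in young control 3 to 8120443 reads in young CCCP 1. Reads assigned to no gene ranged from 20.1% in old control 2 to 65.5% in young CCCP 3, with 62.4% in old control 1. Young CCCP 3 and young control 3 had the lowest median Spearman correlations with the other libraries across 18275 genes, at 0.652 and 0.805. All positions are on GRCm38.

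HSCs of old control mice differed from those of young control mice most clearly in a fall of immediate early genes and a rise of genes of the aged HSC profile. Fos, a subunit of the AP-1 transcription factor, averaged 50.7 ± 6.94 CPM (SD, n = 3) in old controls and 1940 ± 394 CPM (n = 4) in young controls. Clu, which encodes the secreted chaperone clusterin, averaged 331 ± 75.4 CPM in old controls and 42.9 ± 16 CPM in young controls. By the edgeR quasi-likelihood test, 415 of 24523 genes were called, 128 higher and 287 lower in old controls. An unadjusted p below 0.05 was found for 3487 genes, and DESeq2 called 1418, 648 higher and 770 lower.

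Of the 24 measured immediate early genes, transcription factors and feedback regulators induced rapidly by stimulation, 19 fell and none rose over all genes tested in edgeR, and 22 fell when adjusted over the list alone. Their median log2 fold change was -3.31 (camera adjusted p = 1.23e-74; adjusted p = 1.05e-06 with an estimated correlation). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) fell with a log2 fold change of -5.26 (SE 0.55, adjusted p = 1.94e-06). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), an early growth response transcription factor, averaged 119 ± 15.3 CPM in old and 1320 ± 352 CPM in young controls (log2 fold change -3.48, SE 0.36, adjusted p = 1.75e-06). Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), an orphan nuclear receptor, averaged 9.43 ± 6.54 and 2590 ± 1190 CPM (log2 fold change -8.11, SE 0.71, adjusted p = 2.01e-07). Klf2 and Nr4a2 fell with log2 fold changes of -5.89 and -4.33. Every old control library lay below every young control library for these genes. As described below, handling that differed between groups cannot be told apart from age, Mito-Q or CCCP as a cause of such shifts.

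Other genes that fell included Skil, a co-repressor of SMAD proteins (log2 fold change -5.57), Rgs2, a regulator of G protein signalling (-4.41), Ctla2a, a cysteine protease inhibitor (-3.41), Tiparp, an ADP-ribosyltransferase (-5.12), Mapk6, an atypical MAP kinase (-3.64) and Fbxo30, a ubiquitin ligase subunit (-3.92). The NF-kB inflammatory list was lower (5 of 24 genes fell; 7 adjusted over the list alone; camera adjusted p = 5.42e-09; adjusted p = 0.00362 with an estimated correlation). Its members included Nfkbiz (-3.37), Rel (-2.96), Tnfaip3 (-3.28) and Socs3 (-5.75). The list of quiescence and cell cycle inhibitors was lower as well, with 5 of 22 genes fallen, 8 when adjusted over the list alone, and adjusted p = 0.0033 with an estimated correlation. It shared 3 genes with the immediate early list, and without them the list was not called (adjusted p = 0.0764). Cdkn1a, which encodes the p21 inhibitor (-4.33), and Btg1, an antiproliferative factor (-1.73), fell.

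Of 56 measured HSC ageing markers, 19 rose and 5 fell, and 36 rose and 5 fell when adjusted over the list alone. The median log2 fold change was 1.58 (camera adjusted p = 8.2e-24; adjusted p = 8.75e-05 with an estimated correlation). The 5 that fell, Egr1, Fosb, Jun, Junb and Nr4a1, were shared with the immediate early list and went against the direction of the ageing list. Among the other 51 genes 19 rose and none fell. Clu (ENSMUSG00000022037, chromosome 14, 65968483 to 65981547) had a log2 fold change of 2.95 (SE 0.35, adjusted p = 1.22e-05). Gpr183 (ENSMUSG00000051212, chromosome 14, 121952551 to 121965195), an oxysterol receptor, averaged 131 ± 37.1 CPM in old and 3.76 ± 3.25 CPM in young controls (log2 fold change 5.08, SE 0.64, adjusted p = 2.64e-05). Cavin2, a caveola component, had a log2 fold change of 2.07, and Nupr1, a stress-induced transcriptional regulator, 3.86. Mt1, a metallothionein, rose by 3.54 on the log2 scale.

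The megakaryocyte and platelet list was higher, with 7 of 24 genes risen and also 7 when adjusted over the list alone (camera adjusted p = 6.49e-07; adjusted p = 0.000775 with an estimated correlation). Selp, which encodes P-selectin, rose with a log2 fold change of 3.16, and Vwf, which encodes von Willebrand factor, with 1.66. Further genes that rose were Plscr2, a phospholipid scramblase (3.95), Clca3a1 (3.03), Zg16, a lectin (5.78), Smim6 (2.81), Avpi1 (2.50) and Prtn3, a granule protease (2.23). HSC identity genes were not called as a list (adjusted p = 0.112), though Mycn, Sult1a1 and Vwf rose. Cd34, a progenitor and endothelial surface marker, fell from 379 ± 68.9 to 131 ± 22.7 CPM (log2 fold change -1.54).

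Nuclear genes of mitochondrial respiration and translation were called as lists with few called members. Transcripts of mitochondrial DNA were not called and had a negative median (-0.27, adjusted p = 0.85), with young control 3 at a list mean of 8.29 log2 CPM, the other young controls at 5.72 to 5.92 and old controls at 5.64 to 7.04. Complex I nuclear subunits were higher, with none of 36 genes called over all genes or adjusted over the list alone (camera adjusted p = 6.42e-07; adjusted p = 0.636 with an estimated correlation). The mitochondrial ribosome list was higher, with 3 of 77 genes risen and 10 when adjusted over the list alone (camera adjusted p = 5.48e-14; adjusted p = 0.307 with an estimated correlation). Mrps35 (1.65), Mrps18a (1.33) and Mrpl17 (1.30) were those that rose. Complexes II to IV and ATP synthase were also higher (adjusted p = 0.0023 and 0.0199), with adjusted p = 0.636 and adjusted p = 0.653 with an estimated correlation. Cytosolic ribosomal proteins were higher with none of 81 genes called (adjusted p = 0.694 with an estimated correlation). MHC class II and antigen presentation was higher, with 1 of 24 genes risen and 10 when adjusted over the list alone (adjusted p = 0.133 with an estimated correlation). H2-Eb1, an MHC class II chain, rose from 33.4 ± 11.3 to 165 ± 46.9 CPM. Chromatin regulators, including Tet2 (-2.09) and Kdm6a (-1.70), were lower with 2 of 33 genes fallen (adjusted p = 0.133 with an estimated correlation).

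The lists for the integrated stress response, p53 targets, heat shock, S phase and the spliceosome were lower at adjusted p = 0.0138, 0.00673, 0.00267, 0.011 and 0.0419, with adjusted p = 0.133, 0.133, 0.636, 0.636 and 0.636 with an estimated correlation. Their genes that fell numbered 2, 2, 2, 1 and 0 over all genes and 4, 2, 3, 3 and 3 adjusted over the list alone, and 1 stress response gene rose. Without their shared immediate early gene the stress response and p53 lists were not called (adjusted p = 0.15 and 0.0588). The spliceosome list pointed higher and was not called without old control 1 (adjusted p = 0.857).

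In total 17 of 42 lists were called between old and young controls, 8 higher and 9 lower, and 5 held with an estimated correlation. Gene calls rested on few libraries, with 125 genes without old control 2, 140 without old control 3, 243 without young control 1, 255 without young control 4 and 683 without old control 1. With upper-quartile scaling 190 genes were higher and 237 lower, and the median log2 fold change of all genes moved from 0.16 to 0.28.

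**Figure D1:**
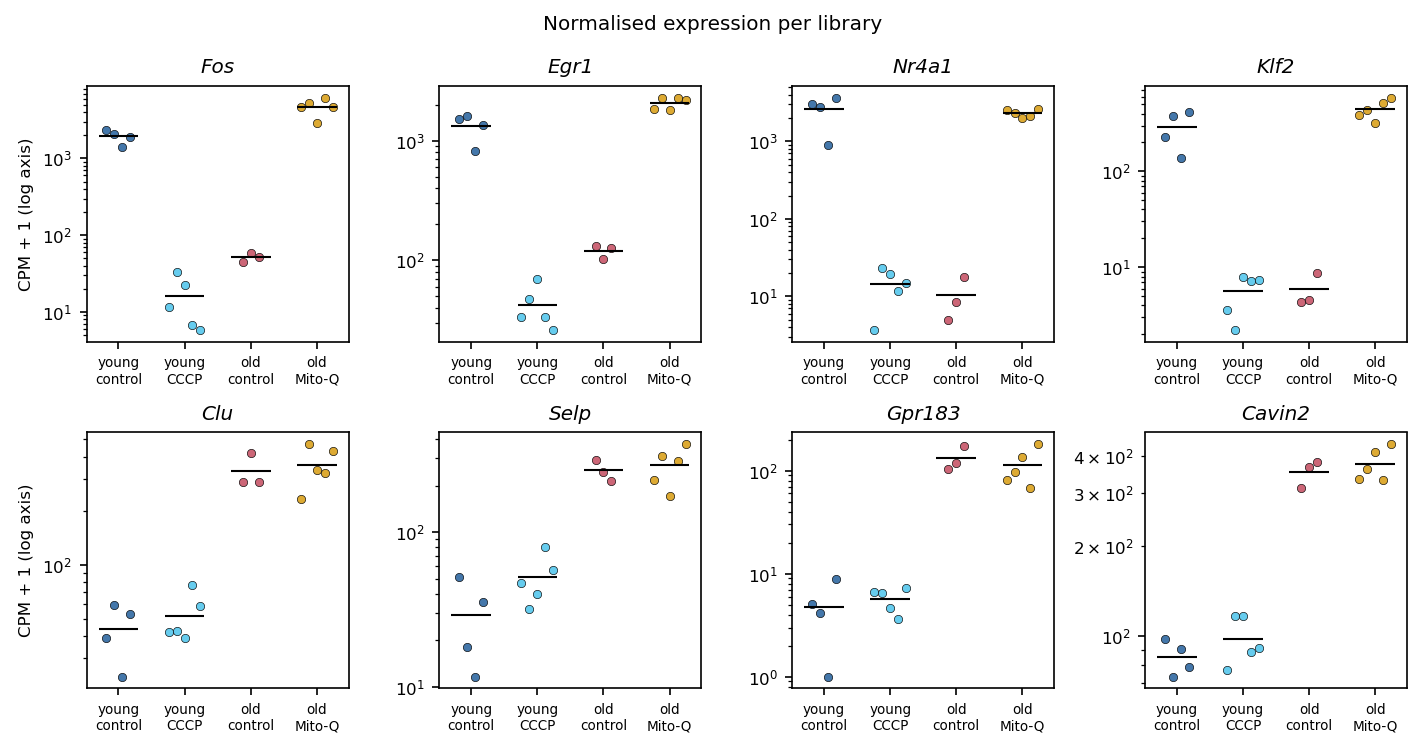
Normalised CPM plus 1 on a log axis for 4 immediate early genes (top) and 4 genes higher in old controls (bottom), with 1 point per library and a line at each group's mean (n = 4 young control, 5 young CCCP, 3 old control, 5 old Mito-Q). Fos averaged 1940 CPM in young controls and 4740 CPM in old Mito-Q libraries, against 14.9 CPM with CCCP and 50.7 CPM in old controls, while Clu averaged 331 and 357 CPM in both old groups.

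HSCs of old mice given Mito-Q carried immediate early transcripts far above those of old controls, whereas markers of HSC ageing such as Clu stayed close to old control levels. Fos averaged 4740 ± 1200 CPM (n = 5) with Mito-Q and 50.7 ± 6.94 CPM (n = 3) in old controls (log2 fold change 6.55, SE 0.58, adjusted p = 1.28e-07). Clu averaged 357 ± 93.4 and 331 ± 75.4 CPM, a log2 fold change of 0.11 that was not called (adjusted p = 0.965). Of 24523 genes, edgeR called 133, of which 129 were higher and 4 lower with Mito-Q. An unadjusted p below 0.05 was found for 2464 genes, and DESeq2 called 545, 383 higher and 162 lower, so the near absence of lower genes was not shared by both tools.

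Of the 24 immediate early genes, 20 rose and none fell with Mito-Q, and 23 rose when adjusted over the list alone. Their median log2 fold change was 4.09 (camera adjusted p = 5.13e-141; adjusted p = 2.44e-08 with an estimated correlation). Egr1 averaged 2070 ± 232 CPM (log2 fold change 4.12), Nr4a1 2320 ± 285 CPM (7.95), Junb 1540 ± 420 CPM (3.73) and Atf3, a stress-induced transcription factor, 638 ± 242 CPM (8.16). Klf2 (6.52), Klf4 (7.22), Fosb (4.48) and Nr4a2 (4.80) also rose. Genes outside that list that rose included Mcl1, an antiapoptotic BCL2 family member (3.13), Bhlhe40, a transcriptional repressor (4.42), Nfkbid (4.36), Skil (5.47) and Tiparp (4.59).

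The NF-kB list was higher, with 5 of 24 genes risen and 6 when adjusted over the list alone (adjusted p = 0.00178 with an estimated correlation). Its members Ptgs2, which encodes cyclooxygenase 2, Socs3, a cytokine signalling inhibitor, and Nfkbiz rose with log2 fold changes of 7.83, 6.69 and 4.54. The integrated stress response list was higher, with 2 of 19 genes risen and 5 adjusted over the list alone (adjusted p = 0.00176 with an estimated correlation). Ppp1r15a, a phosphatase subunit of that response, rose by 3.60 on the log2 scale. Quiescence genes (5 of 22 risen, also 5 adjusted over the list alone; adjusted p = 0.000295 with an estimated correlation) and p53 targets (2 of 19 risen, also 2 adjusted over the list alone; adjusted p = 0.0195 with an estimated correlation) were higher. Cdkn1a and Btg2 were among the risen genes of both lists. Without immediate early members both were still called by camera, with adjusted p = 0.145 with an estimated correlation. Heat shock and ER chaperones were higher, with 3 of 23 genes risen, also 3 when adjusted over the list alone (camera adjusted p = 0.000295; adjusted p = 0.42 with an estimated correlation). These were Dnajb1 (3.06), Dnajb9 (2.51) and Hspa5 (1.68).

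Of the 56 HSC ageing markers 5 rose and none fell with Mito-Q, also 5 when adjusted over the list alone (adjusted p = 0.0195 with an estimated correlation). Each of the 5 was also in the immediate early list. Of the other 51 genes none was called over all genes or adjusted over the list alone, and the list without the shared genes was not called (adjusted p = 0.345). Gpr183 averaged 112 CPM with Mito-Q and 131 CPM in old controls (adjusted p = 0.948). Selp averaged 271 and 251 CPM (adjusted p = 0.973), and Cavin2 375 and 353 CPM (adjusted p = 0.96).

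Lists of nuclear oxidative phosphorylation genes and ribosomal proteins were lower with Mito-Q, with no gene called over all genes, while transcripts of mitochondrial DNA were not called (median log2 fold change -0.05, adjusted p = 0.987). Complex I nuclear subunits had a median log2 fold change of -0.57 (camera adjusted p = 3.43e-06; adjusted p = 0.625 with an estimated correlation). The mitochondrial ribosome, with 1 gene lower when adjusted over the list alone, had a median of -0.60 (camera adjusted p = 5.94e-10; adjusted p = 0.42 with an estimated correlation), and cytosolic ribosomal proteins -0.39 (adjusted p = 0.798 with an estimated correlation). The median over nuclear respiratory and ribosomal genes moved from -0.46 to -0.21 without old control 3, to -0.81 without old control 1 and to -0.72 without old Mito-Q 3. Neutrophil and granule genes were higher, with a median of 2.60 and none of 20 genes called over all genes or adjusted over the list alone (camera adjusted p = 4.21e-08; adjusted p = 0.412 with an estimated correlation). Camp, an antimicrobial granule peptide, ranged widely between Mito-Q libraries at 532 ± 503 CPM, against 35.9 ± 8.89 CPM in old controls (adjusted p = 0.352). The 4 genes that fell were Snhg20, a long noncoding RNA (-2.63), Hist1h1d, a linker histone (-3.27), Luc7l3, a splicing factor (-1.39) and Laptm4a, a lysosomal membrane protein (-1.27).

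Complexes II to IV, ATP synthase and MHC class II were lower as well (camera adjusted p = 0.00241, 0.012 and 0.0452; adjusted p = 0.625 with an estimated correlation in each). Autophagy and lysosome genes were higher (camera adjusted p = 0.0393; adjusted p = 0.625 with an estimated correlation). Chromatin regulators, monocyte and dendritic genes, and myeloid progenitor genes were higher with 1 gene risen in each, namely Tet2 (1.73), Klf4 and Cebpb (1.82). All 3 had adjusted p = 0.412 with an estimated correlation, and 1, 2 and 1 genes rose when adjusted over the list alone. The monocyte list had a negative median (-0.03), with 9 of 19 genes positive. Without Klf4, an immediate early gene, it was not called (adjusted p = 0.181).

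In total 18 of 42 lists were called with Mito-Q, 12 higher and 6 lower, and 6 held with an estimated correlation. The gene count was 79 without old control 2 and 81 without old control 3.

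Young mice given CCCP showed a loss of immediate early transcripts in HSCs relative to young controls. Fos averaged 14.9 ± 11.7 CPM (n = 5) with CCCP and 1940 ± 394 CPM (n = 4) in young controls (log2 fold change -7.02, SE 0.48, adjusted p = 5.73e-10). Neutrophil and granule transcripts were higher as a list (adjusted p = 0.101 with an estimated correlation), with Elane, a serine protease of neutrophil granules, at 429 ± 273 and 2.33 ± 1.02 CPM (log2 fold change 7.5, SE 1.45, adjusted p = 0.0235). Of 24523 genes edgeR called 176, of which 16 were higher and 160 lower with CCCP. An unadjusted p below 0.05 was found for 2735 genes, and DESeq2 called 662, 331 higher and 331 lower, so the excess of lower genes was absent there.

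Of the 24 immediate early genes, 21 fell and none rose with CCCP, and 23 fell when adjusted over the list alone. Their median log2 fold change was -4.26 (camera adjusted p = 6.34e-185; adjusted p = 1.41e-08 with an estimated correlation). Egr1 averaged 40.9 ± 17.4 CPM (log2 fold change -5.01), Nr4a1 13.6 ± 7.52 CPM (-7.58), Fosb 3.96 ± 3.04 CPM (-7.88), and Jun, an AP-1 subunit, fell by 3.84 on the log2 scale. Other genes that fell were Ctla2a (-4.32), Cebpb, a myeloid transcription factor (-3.49), Rgs2 (-4.25), Tiparp (-4.55) and Ccnt1, a cyclin of the transcription elongation factor P-TEFb (-2.20).

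The NF-kB list was lower, with 6 of 24 genes fallen and 9 when adjusted over the list alone (adjusted p = 0.000306 with an estimated correlation). Nfkbiz (-3.39), Rel (-2.44), Tnfaip3 (-2.88) and Socs3 (-4.07) were among them. The integrated stress response list was lower, with 5 of 19 genes fallen, 6 when adjusted over the list alone (adjusted p = 0.00307 with an estimated correlation), including Atf4, a transcription factor and effector of the response (-1.56), and Ppp1r15a (-3.23). Quiescence genes (5 of 22 fallen, also 5 adjusted over the list alone; adjusted p = 4.87e-05 with an estimated correlation) and p53 targets (3 of 19 fallen, 5 adjusted over the list alone; adjusted p = 0.0162 with an estimated correlation) were lower. The median log2 fold change of the p53 targets was -0.05, and turned positive at 0.01 when libraries were scaled by their totals. Cdkn1a (-4.93), Btg2 (-4.30) and Plk2 (-3.28), a polo-like kinase, fell. Without immediate early members the p53 list had adjusted p = 0.101 with an estimated correlation.

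Respiratory and ribosomal lists were lower with CCCP. Transcripts of mitochondrial DNA had a median log2 fold change of -1.30, with none of 12 genes called over all genes and 7 when adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Complex I (adjusted p = 0.444 with an estimated correlation), complexes II to IV (adjusted p = 0.193 with an estimated correlation) and ATP synthase (adjusted p = 0.241 with an estimated correlation) had medians of -0.51, -0.83 and -0.70. Cytosolic ribosomal proteins had a median of -0.76 (adjusted p = 0.34 with an estimated correlation). Without young control 3 the median over nuclear respiratory and ribosomal genes fell to 33.9% of its size, and 17 lists were called in place of 23. In young control 3 the mitochondrial DNA list mean was 8.29 log2 CPM, against 5.72 to 5.92 in the other young controls. Antioxidant genes were lower, with 2 of 24 fallen and 3 adjusted over the list alone (adjusted p = 0.174 with an estimated correlation). These were Prdx6, a peroxiredoxin (-1.19), and Fth1, the ferritin heavy chain (-1.25).

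Neutrophil and granule genes had a median log2 fold change of 3.40 with CCCP. Of 20 genes 1 rose, and 17 did so when adjusted over the list alone (camera adjusted p = 3.24e-17; adjusted p = 0.101 with an estimated correlation). Their mean ran from 4.40 to 8.35 log2 CPM in CCCP libraries and from 1.92 to 4.95 in young controls. Erythroid genes were higher (median 1.05; adjusted p = 0.207 with an estimated correlation), and so were G2 and mitosis genes (median 0.67, none called over all genes, 3 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation). With the neutrophil list as a covariate the erythroid list changed direction and was not called. Genes that rose included Vwf, at 161 ± 47.6 and 67.7 ± 8.94 CPM (log2 fold change 1.25), Zg16 (3.88), Mycn, a MYC family transcription factor (1.97), Ms4a3, a myeloid progenitor gene (5.25), Espl1, which encodes separase (2.92), and Agtr1a, an angiotensin receptor. Agtr1a had no read in any young control and averaged 11.9 ± 18.3 CPM with CCCP, at least 25.8-fold higher than the floor averaged over the control libraries. This bound rested on young CCCP 3 and was 8.28-fold without it, and young CCCP 5, at 0.159 CPM, lay below its own floor of 0.477 CPM.

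Heat shock and ER chaperones were lower (2 of 23 genes fallen, 5 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). So were the spliceosome (1 of 38, 3 adjusted over the list alone; adjusted p = 0.097 with an estimated correlation) and RNA polymerase II and elongation (1 of 42, 2 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). Autophagy, mitochondrial import and mitochondrial ribosome lists were lower with no gene called over all genes, with adjusted p = 0.222, 0.565 and 0.566 with an estimated correlation. S phase and mast cell genes were higher, with adjusted p = 0.566 and 0.182 with an estimated correlation.

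The HSC ageing list was called lower (2 of 56 risen, 5 fallen; 3 and 6 adjusted over the list alone; adjusted p = 0.066 with an estimated correlation), while its median log2 fold change was 0.04. The 5 that fell were shared with the immediate early list, and without them the list pointed higher and was not called (adjusted p = 0.415). Clu averaged 50.9 CPM with CCCP and 42.9 CPM in young controls (adjusted p = 0.83), and Gpr183 4.72 and 3.76 CPM (adjusted p = 0.898). In total 23 of 42 lists were called, 5 higher and 18 lower, and 5 held with an estimated correlation. With the neutrophil list as a covariate 65 genes were called.

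**Figure D2:**
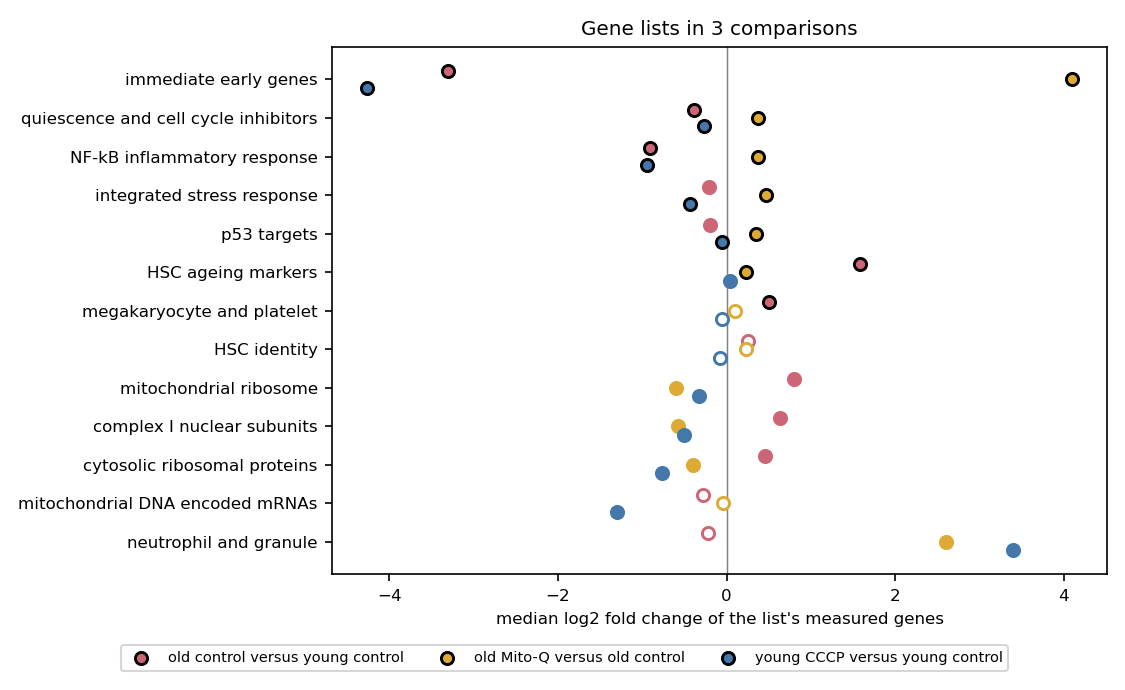
Median log2 fold change of the measured genes of 13 lists in 3 comparisons. Filled points were called by camera at the preset correlation, and a black outline marks lists also called with an estimated correlation. The immediate early list had medians of -3.31, 4.09 and -4.26.

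Old Mito-Q libraries were also set beside young controls to ask which differences of the old controls remained. Genes of the aged HSC profile were higher in old Mito-Q libraries. Clu averaged 357 ± 93.4 CPM (n = 5) against 42.9 ± 16 CPM (n = 4; log2 fold change 3.05, SE 0.33, adjusted p = 3.39e-05), and Gpr183 112 ± 45.5 against 3.76 ± 3.25 CPM (4.85, SE 0.61, adjusted p = 0.000131). Selp (3.27), Cavin2 (2.16), Plscr2 (4.08) and Clca3a1 (3.15) rose. Flt3, a receptor kinase of multipotent progenitors, fell from 101 ± 27.9 to 11.1 ± 2.18 CPM (-3.19), and Cd34 (-1.35) and Vegfa (-2.05) fell. By edgeR 35 genes were called, 32 higher and 3 lower, against 1935 at an unadjusted p below 0.05 and 221 by DESeq2 (154 higher, 67 lower). Of the 32 higher genes 26 were also higher in old controls, where 0.167 would be shared if calls were independent, a figure that disregards the shared young controls.

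Of 56 HSC ageing markers 18 rose and none fell, and 47 rose when adjusted over the list alone (camera adjusted p = 9.2e-89; adjusted p = 8.34e-08 with an estimated correlation). Megakaryocyte and platelet genes were higher (3 of 24 risen, 8 adjusted over the list alone; adjusted p = 4.54e-05 with an estimated correlation). Immediate early genes were higher as a list with a median log2 fold change of 0.64 and none of 24 called over all genes, 8 adjusted over the list alone (adjusted p = 0.0216 with an estimated correlation). Neutrophil genes were higher (1 of 20 risen, 7 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), as were HSC identity genes (3 of 35 risen, also 3 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation) and the integrated stress response (1 of 19 risen, 4 adjusted over the list alone; adjusted p = 0.0699 with an estimated correlation). MHC class II, mast cell, mitochondrial ribosome and cytosolic ribosomal lists were higher with no gene called over all genes (adjusted p = 0.272, 0.17, 0.97 and 0.97 with an estimated correlation). Chromatin regulators, S phase and spliceosome genes were lower with no gene called (adjusted p = 0.608, 0.608 and 0.379 with an estimated correlation). Lists for the TCA cycle, glycolysis, fatty acid oxidation, cholesterol synthesis, mitochondrial biogenesis, mitochondrial dynamics, the interferon response, MYC and ribosome biogenesis, lymphoid progenitors, B cells, T and NK cells, endothelium and stroma were called in none of the 4 comparisons. The lowest camera adjusted p among them was 0.0508, for lymphoid progenitors in old versus young controls.

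In total 13 of 42 lists were called, 10 higher and 3 lower, and 3 held with an estimated correlation. The gene count was 14 without young control 1, 20 without young control 4, 21 without young control 2 and 21 with the neutrophil list as a covariate.

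The treatments were then compared with ageing gene by gene. Genes lower in old controls and higher with Mito-Q numbered 115, against 1.51 if calls were independent, and genes lower in old controls and lower with CCCP numbered 103, against 1.87. Both pairs of comparisons share control libraries, which raises such overlaps. Genes higher with Mito-Q and lower with CCCP numbered 90, against 0.842, and this pair shares no library. The figures for independent calls treat every tested gene as equally likely to be called, although genes differ in expression and spread. A set of 84 genes met all 3 conditions, 18 of them in the immediate early list.

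Of the 415 ageing genes, 400 had the opposite sign with Mito-Q (96.4%, interval 94.1% to 98.0%). The simulations without a treatment effect gave a median of 73.1% and a highest share of 76.4%, and those with 1 level per age 80.4% and 88.9%. The former called a median of 1286 ageing genes (1147 to 1431), a larger set, so their shares are not the value without effect for 415 genes. The number called with 1 level per age was not recorded, so those shares may rest on sets of another size. Both kinds drew genes independently, so their ranges are narrower than correlated genes would give. All 287 genes lower in old controls had the opposite sign, and 115 of them were called higher with Mito-Q. The simulated share of lower genes had a median of 71.3% and a highest of 75.1%, and with 1 level per age a median of 92.9% and a highest of 100%. Of the 128 genes higher in old controls 113 had the opposite sign (88.3%), with a median log2 fold change of -0.75, and 2 were called lower with Mito-Q. Simulated medians for these were 74.9% and 75.8%, and the highest shares 79.9% and 85.7%. With CCCP 349 of the 415 genes had the same sign as in ageing (84.1%, interval 80.2% to 87.5%), beside simulated medians of 68.0% and 76.9% and highest shares of 72.1% and 86.3%, the latter above the real share. Leaving out 1 library in turn moved this share between 61.4% and 95%, beyond the interval, which treats genes as independent. This share was 93.0% for the genes lower in old controls, beside simulated medians of 65.3% and 80% and highest shares of 70.1% and 93.9%. It was 64.1% for those higher, beside simulated medians of 70.5% and 75.6%, and below the lowest share of the former simulations (65.35%). With young controls divided so that no library was shared, the same sign was found for a median of 87.2% of ageing genes (78.1% to 90.1%), with 148 to 228 genes called per division. Without the immediate early list the shares were 96.2% and 83.3%.

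Across all 24523 genes, which are not independent replicates, the log2 fold changes of ageing and Mito-Q correlated with r = -0.621 (Spearman -0.643), and simulations without any effect gave a mean of -0.626. Their covariance was -2.16 against a simulated -1.49. Ageing and CCCP gave r = 0.523 (Spearman 0.419; simulated mean 0.48), with a covariance of 1.65 against 1.01. Without old control 1 the r of ageing and CCCP was 0.248. With young controls divided so that no library was shared, r had a median of 0.141 and ran from 0.108 to 0.176 over 6 divisions. Mito-Q and CCCP gave r = -0.118 (Spearman -0.123), beside simulated values between -0.0182 and 0.0288, but without old control 1 r was 0.101. The simulations drew each gene independently and lack the correlation between real genes, so their range is too narrow to decide.

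**Figure D3:**
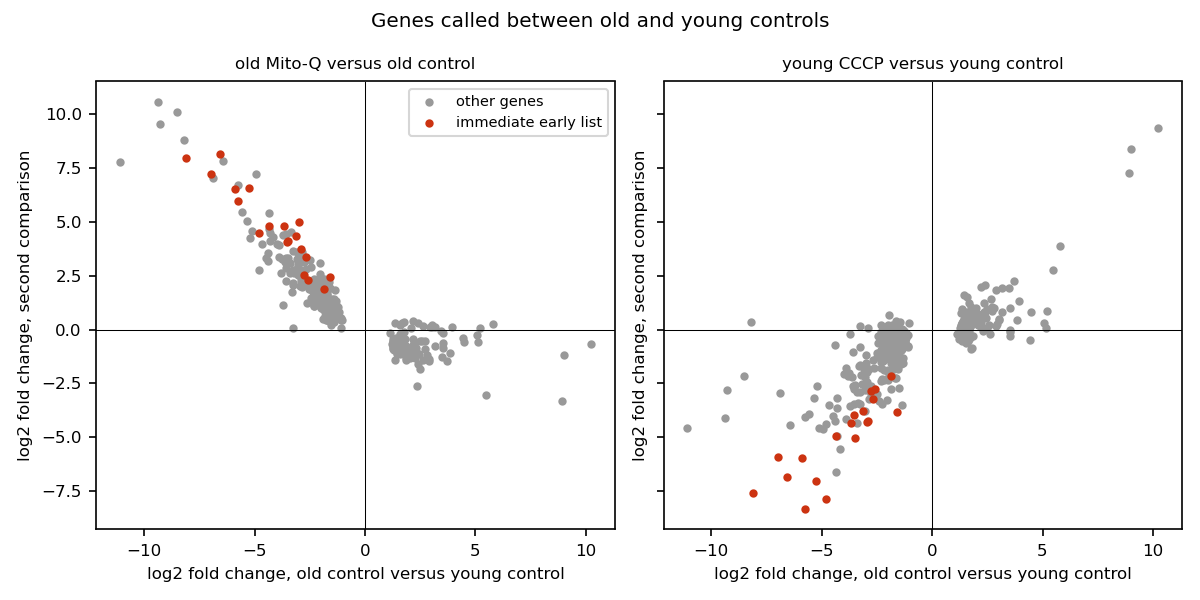
Log2 fold changes of the 415 genes called between old and young controls (horizontal axis) against those of Mito-Q versus old control (left) and CCCP versus young control (right), with immediate early genes in red. With Mito-Q 96.4% lay on the opposite side of 0 from ageing, and with CCCP 84.1% lay on the same side. In 8 genes a group had no reads, so their plotted fold change depends on the fit's prior count.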

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

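The tests of handling, of exchanged labels and of replicate numbers were chosen only after the results were seen, and the remaining tests were stated before theirs.

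Gene counts were compared with other splits of the same libraries. For old versus young controls chance was not excluded, since 2 of 35 splits gave at least the real 415 genes and the highest other gave 744. That split exchanged old control 1 with young control 3. An exchange of their labels was neither shown nor excluded. Of 1280 genes called between the ages without both libraries, immediate early genes left out, 30.2% lay nearer to the labelled age in old control 1 and 57.3% in young control 3. These shares were 14.2% and 50.1% for the 829 genes higher with age, and 59.65% and 70.7% for the 451 lower genes. Lists fixed beforehand went both ways. The immediate early list kept to the labels, with old controls at 4.15 to 4.77 log2 CPM and young controls at 7.57 to 8.28. HSC ageing markers followed the labels, at 6.19 log2 CPM in old control 1 and 4.54 in young control 3, against 6.43 to 6.49 in the other old and 4.95 to 5.06 in the other young controls. Complex I went against them, at 6.55 in old control 1 and 7.60 in young control 3, against 7.62 and 7.94 in the other old and 6.27 to 6.58 in the other young controls. For Mito-Q versus old control a chance division of the libraries was unlikely, as only 1 of 56 splits, the real one, reached 133 genes (highest other 2). It was likewise unlikely for CCCP (1 of 100, 176 genes, highest other 91) and for old Mito-Q versus young control (1 of 100, 35 genes, highest other 2). The splits treat libraries as independent, which the labels do not state, so chance differences between mice are not excluded. For the counts of lists chance was not excluded in any comparison: 8 of 35 splits reached 17 lists (highest other 24), 7 of 56 reached 18 (22), 9 of 100 reached 23 (29) and 20 of 100 reached 13 (17).

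The pattern of most weight was the immediate early list, low in every old control and CCCP library and high in every young control and old Mito-Q library. With the share of reads outside genes as a covariate its median log2 fold change kept at least 96.7% in each of the first 3 comparisons, and with the neutrophil list as a covariate at least 96.2%, which argues against both as the whole cause. Handling that differed between groups, such as the time from marrow collection to lysis, may produce the same pattern, since these genes respond within minutes to cell isolation. The numbers in the deposited names run in a block per group and no handling time is given, so handling cannot be told apart from effects of age, Mito-Q or CCCP, which stay open. The finding that 0 libraries of the low groups reached the list mean of the high groups restates the pattern and decides nothing.

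Neutrophil and granule genes varied between libraries of the same group, at 6.93 ± 1.59 log2 CPM with CCCP and 5.69 ± 1.97 with Mito-Q. Within groups, 11 neutrophil genes outside the primary granule set, not all of them granule genes, moved together. Their median correlation was 0.78, against 0.0595 for random lists (0.327 at the upper end of their central 95%). RNA of neutrophils in the sort is consistent with this, although the gate removes lineage-positive cells. Elane ran from 57.4 to 667 CPM between CCCP libraries and from 3.96 to 534 CPM between Mito-Q libraries. Primary granule genes correlated at 0.595, so a shift of stem cells towards myeloid genes also stays open, untested.

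Oxidative phosphorylation and ribosomal protein genes, 235 in all, moved together with medians of 0.56, -0.46 and -0.57 in the first 3 comparisons. The medians lay outside the central 95% of random lists matched on transcript length and expression level in 3 of 3 comparisons. Those lists had medians of 0.41, -0.28 and -0.35. They were drawn gene by gene and lack the correlation between the real genes, estimated at 0.57 within complex I. Their spread is therefore too narrow to decide, and length and level as the whole cause stay open. Without young control 3 the CCCP median was -0.19, 33.9% of its size, and the ageing median 1.09, 194% of its size. Without old control 1 the ageing and Mito-Q medians were 0.90 and -0.81 (160% and 176%), and without old control 3 they were 0.32 and -0.21 (57.9% and 45.3%), while without old Mito-Q 3 the Mito-Q median was -0.72 (156%). A library effect may thus account for much of the pattern, and a biological difference between groups stays open.

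Each measure was tested in each group large enough for a library far from the others, which gave 20 flags in 141 tests. About 1 in 20 tests, or 7.05 here, would be flagged by chance if the tests were independent. Measures of the same library move together, so whether the flags exceed chance was not tested. All 20 flags fell on libraries of replicate number 3, and old control, with 3 libraries, was too small to be tested. In 5 of 42 lists the same number stood at an end in every group, number 3 being highest for complex I, complexes II to IV, ATP synthase and cytosolic ribosomal proteins and lowest for glycolysis. Numbers permuted within groups gave as many in 2.9% of 1000 draws. Young control 3 stood apart in the share of its 50 most abundant genes (28.8%, others 12.6% to 13.9%) and of mitochondrial transcripts (6.60%, others 1.20% to 1.61%). Its list means in log2 CPM also stood apart for mitochondrial DNA transcripts (8.29), fatty acid oxidation (5.30), antioxidant genes (6.72), MHC class II (5.89), quiescence (6.08) and G2 and mitosis (4.28). Old Mito-Q 3 stood apart in mitochondrial transcripts (4.41%) and in the means of complex I (7.47), ATP synthase (8.19), glycolysis (6.47), NF-kB (4.00), cytosolic ribosomal proteins (9.02) and MYC and ribosome biogenesis (6.45). Young CCCP 3 stood apart in glycolysis (5.93), mitochondrial dynamics (4.84), autophagy (5.37), S phase (5.54) and cytosolic ribosomal proteins (8.50). Its 50 most abundant genes held a larger share (34.9%) than those of young control 3, but this was not flagged beside young CCCP 5 (24.1%). The limma-voom quality weights were lowest in young CCCP 3 (0.258), old control 1 (0.296) and young control 3 (0.302).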

How the results depend on the processing

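The settings that left out libraries by their share of reads outside genes or their correlation, used neutrophil genes as a covariate, separated directions or removed immediate early genes from lists were chosen after the data were seen. The cause of a change was not tested unless fewer libraries or genes account for it. With 3 to 5 libraries per group, few 2-fold changes were called in the simulated data.

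Ageing genes, 415 at first, numbered 648 with the stricter filter, 1418 by DESeq2, 3278 by limma-voom, 186 with only the groups compared, 1208 without the 3 libraries with most reads outside genes and 1293 without the 2 of lowest correlation. Mito-Q genes, 133 at first, numbered 545, 1239, 384 and 323 by DESeq2, by limma-voom and without those 3 or 2 libraries. CCCP genes, 176 at first, numbered 324 with no filter, 65 with the neutrophil covariate, 662 by DESeq2, 360 by limma-voom and 111 with only the groups compared. Old Mito-Q versus young control genes, 35 at first, numbered 90 with no filter, 54 and 69 without those libraries, 21 with the neutrophil covariate, 221 by DESeq2 and 211 by limma-voom. Other settings stayed within 1.5 times, apart from those that left out 1 library.

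Leaving out 1 library in turn gave 125 to 683 ageing genes, 79 to 142 Mito-Q genes, 130 to 185 CCCP genes and 14 to 34 genes of old Mito-Q versus young control, and 15 to 20, 16 to 18, 17 to 23 and 10 to 15 lists. Ageing and Mito-Q then correlated at -0.733 to -0.569, ageing and CCCP at 0.248 to 0.647, and Mito-Q and CCCP at -0.153 to 0.101, reversed without old control 1. The sign shares ran from 91.4% to 98.7% for Mito-Q and from 61.4% to 95% for CCCP, lowest for CCCP without old control 1.

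With an estimated correlation 5, 6, 5 and 3 lists were called in the 4 comparisons, and by fry 9, 6, 12 and 5. Called lists that changed direction were spliceosome in ageing without old control 1 (adjusted p = 0.857, where leaving out 1 library gave 0.00099 to 0.857) and without the 3 libraries (0.967), cytosolic ribosomal proteins with Mito-Q and library total as covariate (0.568), HSC ageing markers with CCCP without immediate early members (0.415), and erythroid (0.67) and neutrophil genes (0.72) with CCCP and the neutrophil covariate. The covariate is the mean of the neutrophil list itself, so the change of that list follows from its construction. None of these lists was called after the change.

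The correlations were -0.726, 0.457 and -0.231 with the stricter filter and -0.769, 0.373 and -0.0553 without the 3 libraries. Without the 2 libraries those with CCCP were 0.546 and -0.0899. With the replicate block they were -0.61, 0.506 and -0.106. Gene counts with the block were 404, 130, 168 and 40. The numbers were not taken to pair samples, as only 3 of 22 pairs of the same number had r above 0.1 (highest 0.204; median 0.0094, against -0.0021 in other pairs). A shift shared by the libraries numbered 3 in some lists is not excluded by that. The Mito-Q share was 98.8% without the 3 libraries, 88.3% for higher and 100% for lower ageing genes. The CCCP share was 76.2% with the stricter filter, 61.6% without the 3 libraries, 67.1% without the 2, 64.1% for higher and 93.0% for lower ageing genes.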

Other observations

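All values in this part were chosen after the data were seen, and no explanation was tested.

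Ddx3y, a Y-linked RNA helicase, averaged 31.5 CPM in old controls, 125 CPM in young controls, 107 CPM in old Mito-Q and 90.3 CPM in CCCP libraries. It fell in old controls with a log2 fold change of -1.99 (edgeR adjusted p = 0.0024) and was higher with Mito-Q by 1.77 (adjusted p = 0.0082). Uty averaged 26.0 CPM in old controls and 84.4 CPM in young controls (adjusted p = 0.0634). Eif2s3y averaged 101 and 141 CPM (adjusted p = 0.575), and Kdm5d 38.9 and 53.1 CPM (adjusted p = 0.807). In old Mito-Q libraries Uty, Eif2s3y and Kdm5d averaged 48.4, 108 and 47.5 CPM, so all 4 genes were on average lower in old controls than in the young control and old Mito-Q groups. This direction was not confined to Y-linked genes. Ddx3x and Kdm6a, X-linked relatives of Ddx3y and Uty, were also called lower in old controls (log2 fold changes -1.33 and -1.70). With Mito-Q their log2 fold changes were 1.15 and 1.25. Whether the 4 Y-linked genes differed from each other was not tested.

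The overlap across comparisons was not confined to the genes of the immediate early list. Without them, 97 genes were lower in old controls and higher with Mito-Q, and 84 were lower in old controls and with CCCP. Both pairs of comparisons share control libraries, which raises such overlaps. For Mito-Q and CCCP, which share no library, 70 genes were higher with Mito-Q and lower with CCCP. Only genes of the list were left out, and Socs3, Nfkbiz and Cdkn1a, called in each of these comparisons, stayed in. Whether the remaining genes belong to the same response as the list was not tested.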
